A study of Mus musculus with 9 samples.

How the data were processed

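RNA from the right ventricle and septum of 9 adult mice on a mixed C57BL/6 background, 5 wild type and 4 Ezh2-deficient, was hybridised to Affymetrix arrays, 1 array per sample. Per the labels, total RNA was isolated with TRIzol and labelled with biotin. The deposited table holds log2 expression values, 1 per probe set and array, which the authors made with Affymetrix Power Tools and RMA, per the submitters' processing notes. RMA as commonly run corrects the background, sets the arrays to 1 distribution and summarises the probes of a probe set by median polish. Versions, library files and settings are not given in the sources used here. That the values are on a log2 scale was read from their range, 2.18 to 15.0, and from the name of the method. The table held 0 other columns of per-sample values. Median polish gives equal values often: 59.9% of probe sets had at least 2 arrays at the same value and 7.12% at least 5. In addition, 472 probe sets repeated all 9 values of an earlier probe set, and the largest such set held 50 probe sets. The table has no detection call or background measure. Y-linked genes averaged 4.84 to 5.50 in the 3 hearts of females and 8.64 to 9.38 in those of males.

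Groups were taken from the description and genotype labels, and replicates were numbered in the order of the samples, so that the numbers pair nothing. The labels speak of 5 and 4 mice, so the samples were treated as separate animals. No batch is recorded, and the letter in the titles was treated as a possible one, as was, after seeing the data, the letter together with the prime that some titles carry. Sex is not recorded and was read from Xist and from Eif2s3y, Kdm5d and Uty, 3 of 4 Y-linked genes planned. For arrays their number limits the precision: the median standard error of a difference was 0.0674 on the log2 scale, and at that standard error a difference of 0.528 was needed to pass.

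Probe sets were named from the platform annotation, with symbols checked through gene identifiers in a reference table of mouse genes, which held the identifiers of 21689 probe sets. Of 28815 probe sets 21780 had 1 gene symbol, 1605 had several and 5430 had none in the annotation used; the last 2 kinds were tested and not named. The 19935 genes were each read at the probe set with the highest mean over all arrays. For Ndufs3 and Eed a further probe set had the same sign.

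The main test was limma's lmFit and eBayes (R 4.3.3 with limma 3.58.1) on the log2 values of all 9 arrays with genotype as the only term, two-sided, adjusted by Benjamini and Hochberg over all 28815 probe sets, with a threshold of 0.05. Differences are Ezh2-deficient minus wild type on the log2 scale, and folds are 2 to the power of that difference. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 30 lists, and also with an estimated correlation and with fry. With the estimated correlation 0 of the lists passed in camera (5 had an unadjusted p under 0.05), with fry's directional test 3 and with its mixed test 10. The lists held 790 entries, of which 727 were measured; the erythrocyte list kept 7 members and lacked the globin genes. A count "adjusted over the list alone" used Benjamini and Hochberg over that list's members. Single values and list means were tested by exact two-sided permutation over all 126 assignments, whose smallest p is 0.00794. Gene lists, the tests and the alternatives were fixed before the data were examined, except where stated.

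Genes were named by a rule fixed beforehand: Ezh2; the up to 12 largest rises and 12 largest falls past the threshold whose groups did not overlap and that had 1 symbol; up to 4 members with the smallest p from each list; and a fixed set of genes always, of which 15 are reported here. The limit of 4 was kept for lists that passed camera and lowered to 1 for the others, a choice made after the list tests were seen. The rule gave 84 genes, of which those that bear on a comparison are named.

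On simulated values drawn from the means and spreads of the 28815 probe sets, the fit for Ezh2-deficient against wild-type hearts recovered 96 of 100 changes of 1 and 81 of 100 changes of 0.5 on the log2 scale, with 5 false calls. The simulated noise was independent between probe sets. Planting so many changes also made the adjusted threshold easier to pass than in the real data, where 10 probe sets passed. In the real fit a difference of 0.528 was needed at the median standard error. The share recovered at 0.5 therefore overstates what the real fit could find. In a simulation on 19935 genes, a list planted with a shift of 0.3 was called higher. Of the lists that share no gene with it 0 were called, and lists that share a gene were not counted. The noise was again independent between genes. The simulation therefore does not show how camera at the preset correlation behaves when genes of a list move together.

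The alternatives were a further quantile normalization, centring on array medians, leaving out probe sets below the median level, keeping probe sets with a gene symbol, 1 probe set per gene, a mean-variance trend with robust eBayes, array weights, the title letter as a block, the Y-linked mean as a covariate, leaving out each array in turn, a change of at least 1.5-fold, and adjusted p thresholds of 0.1 and 0.01. Keeping probe sets with a gene symbol moves nothing for lists and was not applied to them. Fits without arrays that stood apart, within each title letter, with letter and prime as a block, with letter and Y-linked covariate together, and with identical probe sets counted once were added after seeing the data.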

Results

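Gene expression was measured on Affymetrix arrays in the right ventricle and interventricular septum of adult mouse hearts. The 5 wild-type hearts carried floxed Ezh2 alleles without Cre, and the 4 Ezh2-deficient hearts carried floxed alleles together with a Cre recombinase driven by the anterior heart field enhancer of Mef2c. That enhancer is active in embryonic progenitor cells that contribute to the right ventricle, the septum and the outflow tract. Ezh2 is the catalytic subunit of Polycomb repressive complex 2, which methylates histone H3 at repressed genes. The series asks what Ezh2 does in these progenitors for gene expression in the adult heart. The titles of the wild-type samples name a heterozygous floxed genotype, whereas their genotype field names a homozygous floxed one, and the 2 labels were not reconciled here. The table held 28815 probe sets for 9 arrays. Array medians lay between 7.19 and 7.25 on the log2 scale, and Pearson's r between pairs of arrays lay between 0.9897 and 0.9973. By Xist and 3 Y-linked genes, 1 of the 5 wild-type hearts and 2 of the 4 Ezh2-deficient hearts came from females. The titles carry a letter e or x, and the x stands with or without a prime; the labels give the meaning of neither. The letter e marks 2 wild-type and 2 Ezh2-deficient samples, and the letter x marks 3 and 2. The x has a prime in wild-type arrays 3 and 5 and Ezh2-deficient array 2 and none in wild-type array 4 and Ezh2-deficient array 3. Wild-type arrays 4 and 5 lay apart from the other arrays on the first principal component, which held 30.7% of the variance, and Ezh2-deficient array 3 lay apart on the second, which held 24.0%.

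The targeted gene was examined first. The Ezh2 probe set read 8.73 ± 0.12 (SD, n = 5) in wild-type hearts and 8.88 ± 0.11 (SD, n = 4) in hearts labelled Ezh2-deficient, on the log2 scale. The difference of 0.15 (SE 0.07, limma adjusted p = 0.485) was not past the threshold, and an exact two-sided permutation test gave p = 0.0952. Its 95% interval ran from -0.008 to 0.31. Within the samples of title letter e the difference was 0.15, and within letter x it was 0.14. The table gives 1 value per probe set and does not show where in the transcript its probes lie. The tissue also holds cells outside the Cre lineage. The Ezh2 value therefore does not check the genotype labels, and each direction below refers to the groups as labelled. By the labels all Ezh2-deficient hearts and none of the wild-type hearts carried Cre. No difference below can therefore tell loss of Ezh2 apart from an effect of the Cre transgene. The other core members of the complex were also not past the threshold. The difference was -0.11 (SE 0.05, adjusted p = 0.434) for Ezh1, the alternative catalytic subunit. It was -0.14 (SE 0.10, adjusted p = 0.648) for Eed and -0.06 (SE 0.06, adjusted p = 0.795) for Suz12. Across 11 measured subunits of the complex 0 passed by limma, with 1 at an unadjusted p under 0.05, and the list was not past the threshold of limma's camera test (mean -0.04, adjusted p = 0.22).

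The largest rises past the threshold were those of Nrn1, Tnnt1 and Prkcq. Nrn1, which encodes the membrane-anchored protein neuritin, rose 4.51-fold, from 8.09 ± 0.28 (SD, n = 5) to 10.26 ± 0.05 (SD, n = 4; limma adjusted p = 0.000173). Tnnt1, the slow skeletal muscle troponin T, rose 3.81-fold, from 8.30 ± 0.14 to 10.23 ± 0.13 (adjusted p = 2.33e-05). Prkcq, encoding protein kinase C theta, rose 2.38-fold, from 6.93 ± 0.16 to 8.18 ± 0.06 (adjusted p = 0.000294). These 3 genes were called in every one of the 9 fits that left out 1 array, and their differences within letter e were 2.38, 2.06 and 1.31 and within letter x 2.05, 1.81 and 1.22.

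Smaller rises were found for 3 further named genes. Shisa3 rose 1.62-fold (difference 0.70, SE 0.09, adjusted p = 0.041). Tgfb3, a ligand of the transforming growth factor beta family, rose by 0.58 on the log2 scale (SE 0.07, adjusted p = 0.0407). Eya1, a transcriptional coactivator and phosphatase that acts in embryonic progenitor cells, rose 1.49-fold, from 6.36 ± 0.11 to 6.93 ± 0.08 (adjusted p = 0.025). Of the named genes that fell, Acot1, an acyl-CoA thioesterase, was at 0.62 of the wild-type level (difference -0.69, SE 0.09, adjusted p = 0.0448). Stk39, a kinase that acts on cation-chloride cotransporters, was at 0.72 of it (-0.48, SE 0.06, adjusted p = 0.0364), and Arhgap20, a GTPase-activating protein, at 0.73 (-0.45, SE 0.05, adjusted p = 0.0182). Within letter e the differences of Shisa3, Tgfb3, Eya1, Acot1, Stk39 and Arhgap20 were 0.56, 0.49, 0.65, -0.75, -0.38 and -0.46, and within letter x 0.82, 0.65, 0.53, -0.66, -0.56 and -0.44. Their differences hardly moved when each array was left out in turn (0.61 to 0.76 for Shisa3, 0.52 to 0.61 for Tgfb3, 0.54 to 0.61 for Eya1, -0.74 to -0.64 for Acot1, -0.52 to -0.44 for Stk39 and -0.47 to -0.42 for Arhgap20), but with 8 arrays many calls near the threshold were lost. Acot1 lost its call in 9 of 9 fits (adjusted p 0.0542 to 0.152), Shisa3 in all but that without Ezh2-deficient array 4 (up to 0.147) and Stk39 in all but that without wild-type array 2 (up to 0.137). Tgfb3 kept its call only without wild-type array 1 or 5 (up to 0.147 otherwise) and Eya1 only without wild-type array 5 or Ezh2-deficient array 3 or 4 (up to 0.105 otherwise), while Arhgap20 lost it without wild-type array 4 (0.0771), Ezh2-deficient array 1 (0.0829) or Ezh2-deficient array 2 (0.102).

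**Figure D1:**
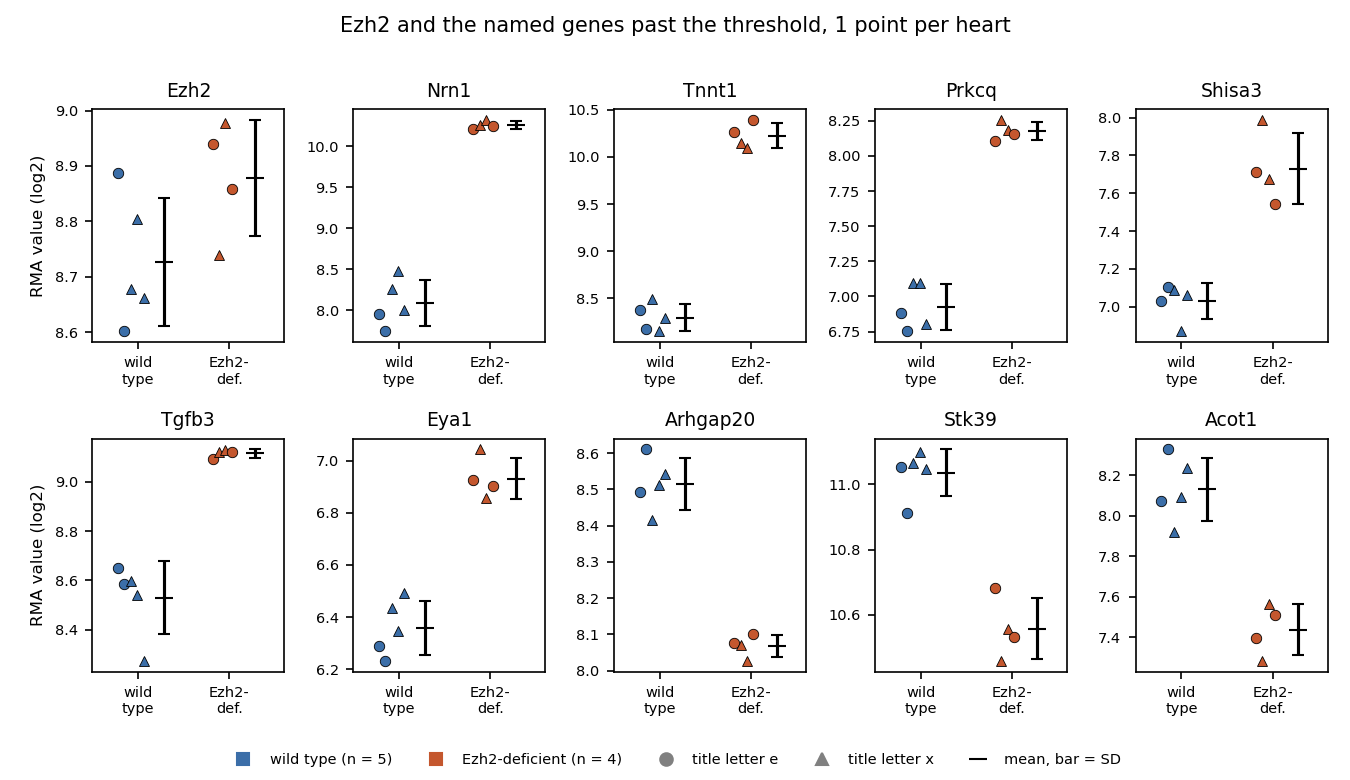
RMA values on the log2 scale (vertical axes, which start at different values) of Ezh2 and the 9 named genes past the threshold, with 1 point per array and the mean ± SD beside the points of the 5 wild-type and 4 Ezh2-deficient arrays. Circles mark title letter e and triangles title letter x; the groups overlap for Ezh2 and are apart for the other genes, such as Nrn1 at 8.09 against 10.26.

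In all, 10 of 28815 probe sets passed limma's test at an adjusted p of 0.05, 7 higher and 3 lower in Ezh2-deficient hearts. The tenth, which was higher, has no gene symbol in the annotation used. At a change of at least 1.5-fold 6 probe sets remained, and at least 2-fold 3, all higher. The 2 groups did not overlap at any of the 10. Over the whole table the groups did not overlap at 3.71% of probe sets, against 1.59% by chance, and 3078 probe sets had an unadjusted p under 0.05, against 1441 with no change. With the title letter as a block 17 probe sets passed, 10 higher and 7 lower, and these held all 10 of the calls. With the mean of the Y-linked genes as a covariate 3 passed, namely Nrn1, Tnnt1 and Prkcq. The other 6 named genes lost their call there with differences close to those without it: Shisa3 0.74 (adjusted p = 0.0641), Tgfb3 0.58 (0.1), Eya1 0.59 (0.0613), Acot1 -0.70 (0.1), Stk39 -0.51 (0.0505) and Arhgap20 -0.44 (0.0613). A further 5 probe sets lay just outside the threshold at an adjusted p of 0.0501. These genes, named after their values were seen, were Rpl3l (-0.95), Prps2 (0.72), Rbfox1 (-0.52), Col8a1 (1.03) and Fitm1 (-0.43).

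Extracellular matrix and fibrosis genes were shifted higher in Ezh2-deficient hearts. Of 44 measured members 43 had a higher mean, and the mean difference over the list was 0.58. Tgfb3 rose; the other 43 did not pass over all probe sets, and 34 members passed as higher when adjusted over the list alone. Postn, which encodes the matrix protein periostin, read 9.94 ± 0.35 in wild-type and 11.31 ± 0.31 in Ezh2-deficient hearts (difference 1.37, SE 0.19, adjusted p = 0.0554). Col8a1, a short-chain collagen, differed by 1.03 (SE 0.14, adjusted p = 0.0501), and the proteoglycan gene Bgn by 0.78 (SE 0.12, adjusted p = 0.093). Some settings called them, such as dim probe sets left out (limma adjusted p = 0.0338 for Col8a1, 0.0366 for Postn). With array weights Postn (0.0476) and Bgn (0.0387) passed. Without 1 array the adjusted p of Postn, Col8a1 and Bgn reached 0.196, 0.196 and 0.264. Col1a1, the main fibrillar collagen chain, differed by 0.84 (SE 0.26, adjusted p = 0.291), with 0.38 within letter e and 1.12 within letter x. The camera test of the list gave an adjusted p = 5.55e-30 with its preset correlation between genes and adjusted p = 0.187 with an estimated correlation. The list mean differed by 0.41 within letter e and 0.69 within letter x. It was lowest in wild-type arrays 4 and 5, which lay apart (-0.39 and -0.56, against -0.27 to 0.04 in the other 3 wild-type arrays), and differed by 0.44 without them. An exact permutation test of the list mean per heart gave p = 0.0159, which became 0.0794 after adjustment over the 30 lists.

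Markers of fibroblasts and endothelium were also shifted higher as lists. Of 15 fibroblast markers 14 had a higher mean (list mean 0.43, camera adjusted p = 2.14e-08, adjusted p = 0.23 with an estimated correlation). Mfap5 differed by 0.80 (SE 0.15) and Pcolce, an enhancer of procollagen processing, by 0.52 (SE 0.16). By limma 0 of the 15 passed over all probe sets, 9 had an unadjusted p under 0.05, and 6 passed when adjusted over the list alone. The matrix list also holds 6 of the 15 markers; the mean difference of the 9 others was 0.34. The list mean differed by 0.18 within letter e and 0.61 within letter x. Of 18 endothelial markers 17 had a higher mean (list mean 0.27, camera adjusted p = 2.77e-06, adjusted p = 0.23 with an estimated correlation). Vwf, encoding von Willebrand factor, differed by 0.75 (SE 0.17) and Eng, encoding endoglin, by 0.43 (SE 0.10); by limma 0 members passed over all probe sets, 6 had an unadjusted p under 0.05 and 6 passed when adjusted over the list alone. The endothelial list mean differed by 0.17 within letter e and 0.34 within letter x. Without wild-type arrays 4 and 5 the differences were 0.33 for fibroblast and 0.19 for endothelial markers. The exact permutation test of the list mean gave p = 0.0159 for either list, and 0.0794 after adjustment over the 30 lists.

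Genes of fatty acid oxidation were shifted lower. All 28 measured members had a lower mean in Ezh2-deficient hearts, with a list mean of -0.27 (camera adjusted p = 2.24e-22, adjusted p = 0.187 with an estimated correlation). Acot1 fell, and 22 members passed as lower when adjusted over the list alone. Mlycd, encoding malonyl-CoA decarboxylase, differed by -0.33 (SE 0.06, adjusted p = 0.12). The auxiliary enzymes of unsaturated fatty acid oxidation Ech1 and Eci1 differed by -0.41 (SE 0.07) and -0.29 (SE 0.05). The list mean differed by -0.21 within letter e, -0.33 within letter x and -0.26 without wild-type arrays 4 and 5. An exact permutation test of the list mean gave p = 0.00794, the smallest that 126 assignments allow, and 0.0794 after adjustment. Oxidative phosphorylation genes were shifted the same way by a smaller amount. All 41 measured members had a lower mean (list mean -0.11, camera adjusted p = 4.85e-12, adjusted p = 0.23 with an estimated correlation). By limma 0 passed over all probe sets, 17 had an unadjusted p under 0.05, and 1 passed when adjusted over the list alone, Sdhd, a subunit of succinate dehydrogenase (-0.24, SE 0.05). Within letter e the list mean differed by -0.07 and within letter x by -0.14, and its exact permutation p was 0.0159 (0.0794 adjusted). By fry, which tests whether a list's own genes move one way on balance, the matrix list (adjusted p = 0.0235), fatty acid oxidation (0.0221) and oxidative phosphorylation (0.0318) were the 3 lists of 30 that passed.

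**Figure D2:**
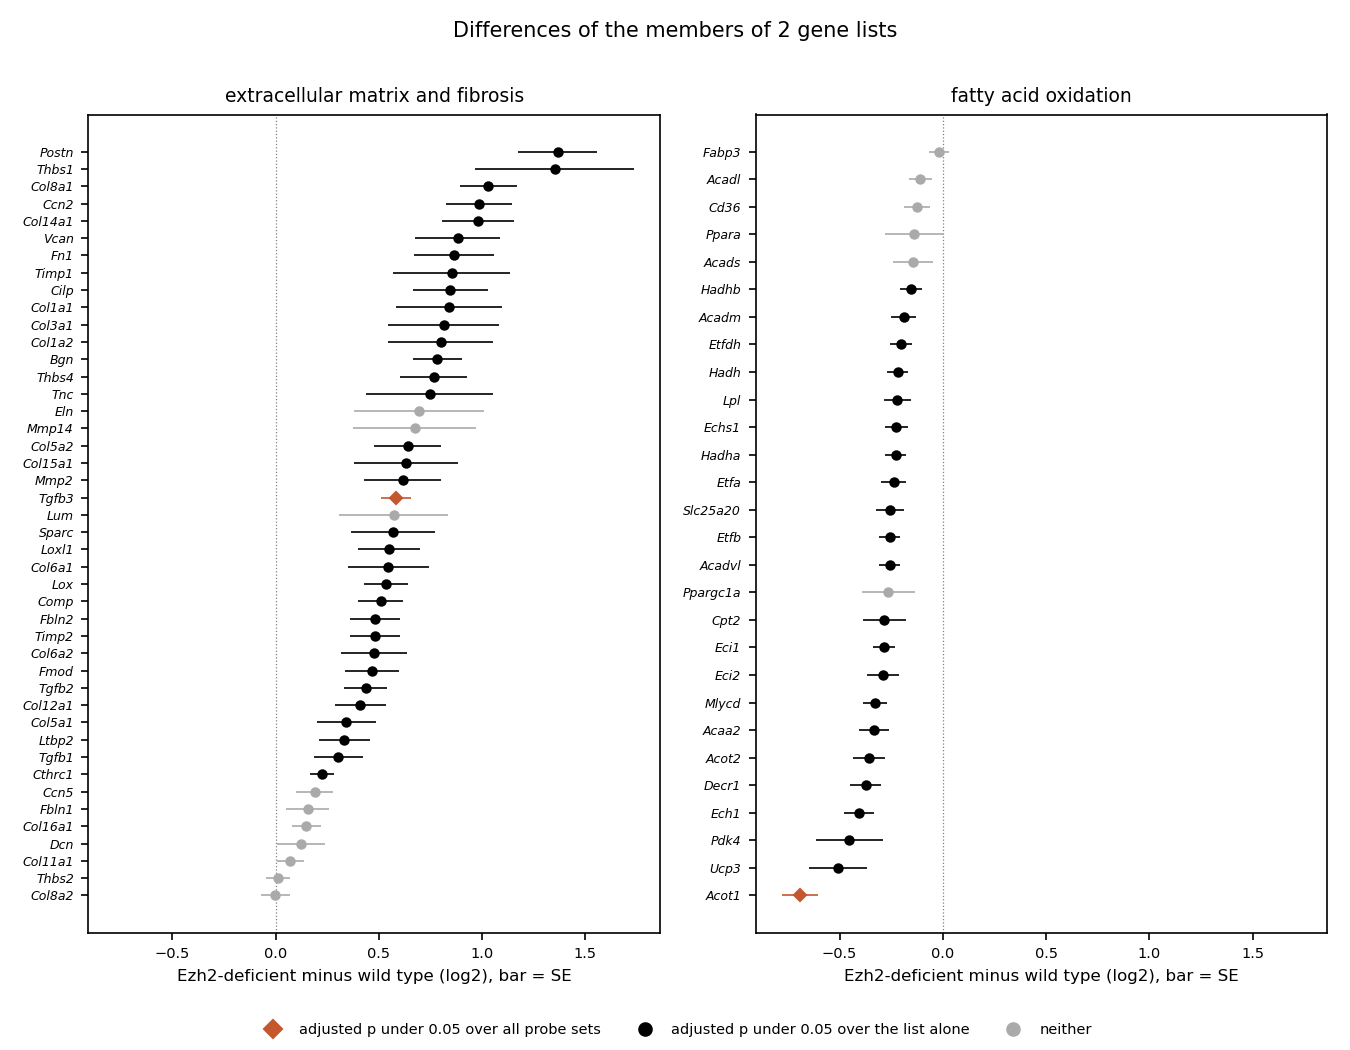
Difference between Ezh2-deficient and wild-type hearts on the log2 scale (horizontal axis, bar = SE) of each measured member of the matrix and fibrosis list (left, 44 genes) and of the fatty acid oxidation list (right, 28 genes). Diamonds mark the members past the threshold over all probe sets (Tgfb3 and Acot1), black points those past it over the list alone and grey points the others; 43 members lie above 0 on the left and 0 on the right.

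Fetal and hypertrophy genes were shifted higher as a list, with 22 of 26 members having a higher mean (list mean 0.34, camera adjusted p = 9.39e-07, adjusted p = 0.372 with an estimated correlation). By limma 0 members passed over all probe sets, 8 had an unadjusted p under 0.05, and 6 passed when adjusted over the list alone. Acta1, skeletal muscle alpha-actin, which also belongs to the fetal heart programme, differed by 1.23 (SE 0.28, adjusted p = 0.17). The natriuretic peptide genes Nppb and Nppa differed by 0.88 (SE 0.22, adjusted p = 0.202) and 0.86 (SE 0.22, adjusted p = 0.222). Myh7, the slow beta-myosin heavy chain, differed by 0.83 (SE 0.26, adjusted p = 0.301) and by 1.15 without Ezh2-deficient array 3, where it passed (adjusted p = 0.0486, against up to 0.665 in other settings). Myh6, the adult mouse alpha-myosin heavy chain, differed by -0.08 (SE 0.06, adjusted p = 0.652). Ccn2 and Ankrd1, which respond to mechanical load, differed by 0.99 (SE 0.16) and 0.51 (SE 0.10). The list mean differed by 0.33 within letter e and 0.31 within letter x, and its exact permutation p was 0.0714 (0.195 adjusted). It was -0.22 in Ezh2-deficient array 3, within the wild-type range of -0.35 to 0.01, and 0.26 to 0.37 in the other 3. Adult ventricular contraction and conduction genes were shifted lower, with 26 of 31 members having a lower mean (list mean -0.11, camera adjusted p = 1.87e-05, adjusted p = 0.406 with an estimated correlation). The potassium channel genes Kcnd2, Kcnip2 and Kcnv2 differed by -0.69 (SE 0.15), -0.30 (SE 0.06) and -0.52 (SE 0.12), 0 members passed over all probe sets by limma, 10 had an unadjusted p under 0.05, and 7 passed as lower and 1 as higher when adjusted over the list alone. This list mean differed by -0.07 within letter e, where it did not pass (adjusted p = 0.0596, the highest of its settings), and by -0.15 within letter x. Without Ezh2-deficient array 3, in which blood markers were high, it differed by -0.06 (adjusted p = 0.0253), and its exact permutation p with all arrays was 0.0318 (0.136 adjusted).

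Many regulators of development are known targets of Polycomb repression. Of 61 measured developmental regulators with CpG islands, Eya1 rose and 60 did not pass, while Eya1 and Alx1 passed when adjusted over the list alone. Alx1, a homeobox gene, differed by 0.48 (SE 0.08, adjusted p = 0.105), Sox9 by 0.27 (SE 0.08) and Twist1 by 0.21 (SE 0.07). In wild-type and Ezh2-deficient hearts, Eya1 (6.36 and 6.93) and Alx1 (6.27 and 6.75) read below every array median. Eya1 was not among the calls with dim probe sets left out. The list mean of 0.05 passed the camera test (adjusted p = 0.0275) but gave adjusted p = 0.588 with an estimated correlation, and its exact permutation p was 0.183. It was 0.003 within letter e and 0.08 within letter x, and it did not pass without Ezh2-deficient array 3 (0.02, adjusted p = 0.526), wild-type array 3 (adjusted p = 0.0626) or wild-type array 4 (0.03, adjusted p = 0.1), with a highest adjusted p of 0.984 over all settings. Of 28 cardiac progenitor and heart field regulators Eya1 rose and 27 did not pass. Isl1, a marker of second heart field progenitors, differed by 0.17 (SE 0.09, adjusted p = 0.553). Its difference was 0.02 within letter e, 0.31 within letter x and 0.08 without Ezh2-deficient array 2. The list was not past the camera threshold (adjusted p = 0.0579, 0.0158 to 0.804 in other settings) but passed without wild-type array 2 (0.031) or Ezh2-deficient array 1 (0.0359), and with all arrays gave adjusted p = 0.372 with an estimated correlation; by fry's mixed test, which counts changes in either direction, it passed (adjusted p = 5.37e-06). By limma 9 of the 28 had an unadjusted p under 0.05. Over this list alone 3 members passed: Eya1, Foxc2 (0.35, SE 0.08) and Hopx (-0.32, SE 0.08), the last 2 of which were named after their values were seen. The 37 measured Hox genes held 0 that passed by limma, with 2 at an unadjusted p under 0.05 (list mean 0.02, camera adjusted p = 0.415), and Cdkn2a, a cell cycle inhibitor locus repressed by Polycomb in many cells, differed by 0.21 (SE 0.07, adjusted p = 0.315). Among 39 skeletal muscle genes Tnnt1 rose and 38 did not pass, while Tnnt1 and Acta1 passed over the list alone. Tnni1, the slow skeletal troponin I, differed by 0.13 (SE 0.07, adjusted p = 0.535). The skeletal muscle list passed fry's mixed test (adjusted p = 1.84e-08). By limma, however, 4 of its 39 members had an unadjusted p under 0.05, against 3078 of all 28815 probe sets. Tnnt1 alone had an unadjusted p of 8.09e-10 by limma, and the list was not tested without it. The list (mean 0.11) did not pass the camera test (adjusted p = 0.0653, 0.0201 to 0.464 in other settings). It passed camera without wild-type array 2 (0.031) or Ezh2-deficient array 2 (0.0201), and with dim probe sets left out (0.30, 0.024). With all arrays it gave adjusted p = 0.588 with an estimated correlation.

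Cell cycle and immediate early genes passed the camera test as higher, although their means per heart overlapped between the groups. The immediate early list was set up as a marker of tissue handling, and handling was not tested as a cause. Of 34 cell cycle genes 33 had a higher mean (list mean 0.30, camera adjusted p = 4.24e-11, adjusted p = 0.372 with an estimated correlation). Ccnd2, encoding cyclin D2, differed by 0.39 (SE 0.08, adjusted p = 0.129) and was the 1 member that passed over the list alone. All 25 immediate early genes had a higher mean (list mean 0.41, camera adjusted p = 2.34e-10, adjusted p = 0.372 with an estimated correlation). Ier2 differed by 0.37 (SE 0.09) and Jund by 0.25 (SE 0.06), and 5 members passed over the list alone. By limma 0 members of either list passed over all probe sets, and 13 and 7 had an unadjusted p under 0.05. The cell cycle list mean differed by 0.21 within letter e and 0.32 within letter x, and the immediate early list mean by 0.33 and 0.38. Exact permutation of the list mean gave p = 0.0635 for cell cycle and 0.111 for immediate early genes (0.191 and 0.278 adjusted). Without wild-type arrays 4 and 5 the differences were 0.16 and 0.20, and without Ezh2-deficient array 1 that of immediate early genes was 0.27.

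Other cell types were examined through their markers. Epicardial and mesothelial markers (list mean 0.20, camera adjusted p = 0.00233, adjusted p = 0.406 with an estimated correlation) differed by 0.02 within letter e and 0.38 within letter x, and did not pass without Ezh2-deficient array 3 (0.09, adjusted p = 0.246). Krt18 and Wt1 differed by 0.38 (SE 0.10) and 0.31 (SE 0.12). Macrophage and monocyte markers (0.11, camera adjusted p = 0.00346, adjusted p = 0.588 with an estimated correlation) differed by -0.05 within letter e and 0.29 within letter x, and did not pass without Ezh2-deficient array 3 (0.04, adjusted p = 0.127) or without wild-type array 5 (0.05, adjusted p = 0.0544). Their mean was 0.06 without Ezh2-deficient array 2 and 0.18 without Ezh2-deficient array 1 or 4. Adgre1, encoding the F4/80 antigen, differed by 0.19 (SE 0.10). Smooth muscle and pericyte markers differed by 0.11 (camera adjusted p = 0.0275, adjusted p = 0.537 with an estimated correlation) and did not pass with the Y-linked covariate (adjusted p = 0.0646) or without wild-type array 5 (0.06, adjusted p = 0.125), Ezh2-deficient array 1 (adjusted p = 0.106) or Ezh2-deficient array 4 (0.08, adjusted p = 0.214). Their member with the smallest p, Abcc9, differed by -0.18 (SE 0.07). The interferon response list passed as higher (0.09, camera adjusted p = 0.00386, adjusted p = 0.588 with an estimated correlation), although the 1 member that passed over the list alone was lower. That member was Iigp1, an immunity-related GTPase (-1.02, SE 0.18, adjusted p = 0.118, 0.0489 to 0.651 in other settings), which passed with title letter and prime as a block. The interferon list did not pass without wild-type array 2 (0.04, adjusted p = 0.0886), and its mean was 0.05 without wild-type array 5 and 0.15 without wild-type array 3. The exact permutation p of the list mean was 0.0635 for epicardial, 0.405 for macrophage, 0.238 for smooth muscle and 0.373 for interferon genes. By limma 0 members of these 4 lists passed over all probe sets; an unadjusted p under 0.05 was found for 4 epicardial, 0 macrophage, 1 smooth muscle and 3 interferon members. Lymphocyte (0.12, camera adjusted p = 0.0501), erythrocyte (0.26, 0.139) and atrial markers (0.09, 0.22) did not pass. The lymphocyte list passed without wild-type array 4 (0.16, adjusted p = 0.00248) or Ezh2-deficient array 1 (0.15, 0.0174), 2 (0.16, 0.0153) or 4 (0.17, 0.0075), and was 0.01 without Ezh2-deficient array 3 (0.906, the highest of its settings). The atrial list passed without Ezh2-deficient array 1 (0.22, adjusted p = 0.0436) or 3 (0.17, 0.0253) and was -0.07 without Ezh2-deficient array 2 (0.981, the highest of its settings) and -0.05 without wild-type array 3. With all arrays the lymphocyte and atrial lists gave adjusted p = 0.625 and adjusted p = 0.668 with an estimated correlation. The erythrocyte list mean was 0.04 without Ezh2-deficient array 3. In Ezh2-deficient array 3 the erythrocyte list mean was 0.78 and the lymphocyte list mean 0.41, above the other 8 arrays.

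With the title letter as a block all 14 lists passed camera at the preset correlation. Without the block 0 of them passed with an estimated correlation (5 of 30 had an unadjusted p under 0.05), and 33 of 100 splits of the arrays called as many lists at the preset one. With the block the mean differences were 0.56 for extracellular matrix and fibrosis genes, -0.27 for fatty acid oxidation, -0.11 for oxidative phosphorylation, 0.27 for cell cycle genes and 0.36 for immediate early genes. They were 0.42 for fibroblast markers, 0.26 for endothelial markers, 0.32 for fetal and hypertrophy genes, -0.11 for adult ventricular contraction and conduction genes and 0.22 for epicardium and mesothelium markers. For macrophage and monocyte markers the blocked difference was 0.13, for the interferon response 0.10, for smooth muscle and pericyte markers 0.10 and for developmental regulators with CpG islands 0.05. Cardiac progenitor and heart field regulators (camera adjusted p = 0.0358), the unfolded protein and heat shock response (0.0237) and lymphocyte markers (0.0345) passed with this block as well, and all 17 passed with letter and prime as a block. Without a block these 3 gave adjusted p = 0.372, adjusted p = 0.625 and adjusted p = 0.625 with an estimated correlation.

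**Figure D3:**
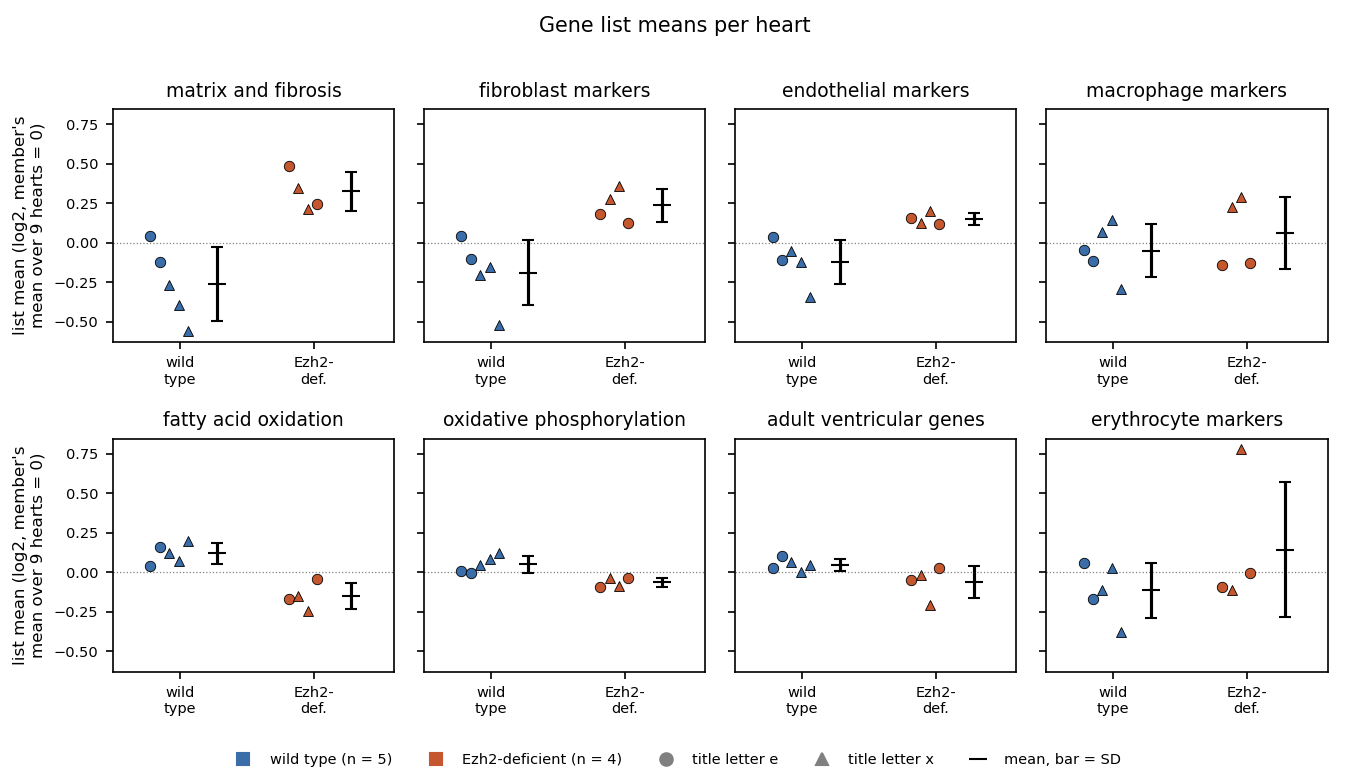
Mean of each of 8 gene lists per array on the log2 scale (vertical axes), after each member's mean over the 9 arrays was set to 0, with the mean ± SD beside the points of the 5 wild-type and 4 Ezh2-deficient arrays. The matrix list lies at 0.22 or above in the Ezh2-deficient arrays and at 0.04 or below in the wild-type arrays; the erythrocyte list stands at 0.78 in Ezh2-deficient array 3, a triangle.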

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

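The tests of title letter, prime, sex and cell type share and the interval for Ezh2 were chosen after the results were seen, as were the count of splits with identical probe sets counted once and the comparison of platelet genes with wild-type array 4; the other splits, the left-out arrays and the platelet genes were set before. Within groups of 4 or 5 arrays, 228 sets of values were searched for 1 array far from the rest, and 14 were found against about 11 by chance, since chance marks about 1 group in 20.

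Ezh2-deficient array 3 accounted for several of these. Its erythrocyte list mean was 0.78, against -0.11 to 0 in the other 3 Ezh2-deficient arrays, its lymphocyte list mean 0.41, against -0.08 to -0.02, its Alas2 value 11.57, against 9.15 to 9.27, and its Csf3r value 6.69, against 6.45 to 6.49. Blood carried over in the tissue is a candidate explanation; a first test of it, in which 22 of 39 blood markers were highest in this array, used the lists of the pattern itself, decides nothing and was replaced. In the replacement, 8 measured genes of a list of 12 platelet genes, which play no part in the pattern, were each higher in this array than the mean of the other 3 Ezh2-deficient arrays, on average by 0.429 on the log2 scale, against a 95th percentile of 0.129 over 10000 random lists matched on level. Yet the platelet genes were as high in wild-type array 4 (mean 7.84, against 7.79 in this array, with 4 of the 8 above it). Wild-type array 4 alone shares its title x without a prime, and these 2 were also the only x arrays from females. They were close in the neutrophil and mast cell list (0.21 and 0.20) and ribosome list (0.22 and 0.26). Wild-type array 4 had the next highest lymphocyte list mean (0.11) and Alas2 value (9.75) but an erythrocyte list mean of 0.03. Blood, an effect shared by these 2 arrays, whether of sex or of what the title marks, and a biological cause in this animal stay open. The last 2 were not tested.

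The Ezh2 probe set was not lower in hearts labelled Ezh2-deficient. Against 1 mislabelled array or 2 swapped arrays, each array was left out in turn and placed by the 20 probe sets with the smallest p among the other 8 arrays, and 9 of 9 lay on the side of their own group. This does not address an exchange of both whole groups. Whether probes outside the deleted part, or RNA of cells that keep the gene, hide a fall cannot be told apart, because the table has no value per probe; the lower 95% bound of the whole probe set's difference was -0.008.

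Matrix genes were shifted higher and fatty acid oxidation genes lower by camera at the preset correlation. By limma 1 of 44 and 1 of 28 members passed. Each list gave a camera adjusted p = 0.187 with an estimated correlation and 0.0794 by exact permutation over the 30 lists. That permutation could hardly pass: its smallest p, 0.00794, stays above 0.05 after adjustment unless several other lists also have a low p. By fry's directional test both lists passed (adjusted p = 0.0235 and 0.0221). A lower share of cardiomyocytes would raise the markers of other cell types alike. The fibroblast list exceeded the mean of the endothelial, smooth muscle and macrophage lists by 0.26 more in Ezh2-deficient hearts (exact permutation p = 0.01587). Without each array this was 0.23 to 0.30 (p up to 0.0357). Exact permutation gave p = 0.01667 within letter, 0.02778 within letter and prime and 0.0444 within sex. Yet Abcc9, a member of the smooth muscle list, was bright in wild-type hearts (11.83) and differed by -0.18. If that list also reads cardiomyocyte RNA, a lower share would itself lower it, so this contrast cannot decide. Letter x carried most of the contrast, with 0.38 against 0.10 within letter e. Against the endothelial list alone the fibroblast excess was 0.156 (exact p = 0.0397), and 0.01 within letter e. It passed within letter (exact p = 0.0333) but not within sex (0.0667) or within letter and prime (0.0556). Without Ezh2-deficient array 3 its exact p was 0.125. With the 6 of 15 markers shared with the matrix list left out, the first contrast was 0.18 (exact p = 0.0238). That did not pass within sex (0.0667), within letter and prime (0.0556) or without any 1 array (up to 0.0571) other than wild-type array 1 or Ezh2-deficient array 4. A lower share of cardiomyocytes therefore stays open for the hearts of both letters. The fatty acid oxidation list differed from the adult ventricular list by -0.163 (exact p = 0.007937, the smallest possible), although very bright contractile genes may be compressed. Permuting genotype within sex gave an exact p of 0.02222 for both the matrix list (0.60) and fatty acid oxidation (-0.24). Within title letter it was 0.01667 for both (0.56 and -0.27), and within letter and prime 0.02778 for both (0.57 and -0.27). Each is the smallest its 45, 60 or 36 assignments allow. Both lists were picked from the 30 after their values were seen, and these p are not adjusted for that. The shifts thus remained with sex, letter, or letter and prime held fixed singly. Chance over the 30 lists was not excluded. For the matrix genes a lower share of cardiomyocytes, a larger share of fibroblasts and a change within them stay open. An effect of genotype stays open for both lists, and in it loss of Ezh2 cannot be told apart from the Cre transgene. Within letter x the arrays with a prime came from males and those without from females. There sex and prime cannot be told apart, and letter and prime held sex fixed as well. Within letter e sex was not held fixed by it. Over all arrays, sex and letter together were examined only as covariates.

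The other values far from the rest of their group were, in wild-type array 5, Tgfb3 at 8.27 (8.54 to 8.65 in the rest), Eng at 10.16 (10.51 to 10.57) and the smooth muscle list mean at -0.26 (-0.02 to 0.03). In wild-type array 2, Stk39 stood at 10.91 (11.05 to 11.10) and Kcnd2 at 9.63 (8.96 to 9.07). In wild-type array 3 the atrial list mean was -0.61 (0.03 to 0.20). In Ezh2-deficient array 1, Epcam was 6.09 (5.98 in the rest) and the interferon list mean -0.07 (0.08 to 0.10). Kcnv2 was 6.86 in Ezh2-deficient array 2 (6.65 to 6.67), and Eed was 8.20 in Ezh2-deficient array 4 (8.42 in the rest).

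Of 100 splits of the 9 arrays into 4 and 5, 2 called at least as many probe sets as the real split, itself included. For the total count, chance can thus be excluded at a share of 0.05. This does not hold for each of the 10 calls taken singly. The real split called 10 and the highest other 53. A split with so many calls points to a structure in the data: it exchanges wild-type array 2 and Ezh2-deficient array 1, and 50 of its 53 calls are 1 set of values repeated over 50 probe sets, so that it called 0 by limma with identical probe sets counted once. With identical probe sets counted once, the real split called 16 and the highest other 3, and 1 of 100 splits, the real one, reached that count. For gene lists chance cannot be excluded: 33 of 100 splits called at least the 14 lists of the real split with the preset correlation, and the highest other called 18.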

How the results depend on the processing

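Fits without the arrays that stood apart, within a title letter, with letter and prime as a block, with letter and covariate together, and with identical probe sets counted once were chosen after seeing the data. Where the cause of a change is not named, the cause was not tested. The direction of the 10 calls was the same in every setting that tested them. The Ezh2 difference stayed between 0.107 and 0.198 and past no threshold. The count of 10 probe sets (7 higher, 3 lower) became 17 (10 and 7) with arrays centred on their medians, with dim probe sets left out and with the title letter as a block. It became 19 (12 and 7) with probe sets that have a gene symbol and also with 1 probe set per gene, and 16 (10 and 6) with identical probe sets counted once; these 3 settings test fewer probe sets. It became 27 (18 and 9, the 10 calls among them) with letter and prime as a block, 37 (26 and 11) with array weights and 24 (16 and 8) at an adjusted p of 0.1. It fell to 6 (5 and 1) at 1.5-fold, 3 (3 and 0) at an adjusted p of 0.01 and 3 (3 and 0) with the Y-linked covariate. With fewer arrays it was 5 (5 and 0) without wild-type arrays 4 and 5, and 6 (6 and 0) without these and Ezh2-deficient array 3. With letter and covariate together it was 5 (5 and 0). By limma it was 0 (0 and 0) within letter e and 0 (0 and 0) within letter x, where 2183 and 3132 probe sets had an unadjusted p under 0.05. Quantile normalization again gave 10 (8 and 2), so that centring moved the share of higher calls from 70% to 58.8% and quantile normalization to 80%. Leaving out each array gave 3 to 15 in all, 3 to 10 higher and 0 to 5 lower. It was 3 without wild-type array 4, Ezh2-deficient array 1 or Ezh2-deficient array 2, 4 without wild-type array 3, 5 without wild-type array 2 and 15 without Ezh2-deficient array 4. Nrn1, Tnnt1 and Prkcq were the genes kept in each of these 9 fits. The 14 gene lists became 0 with an estimated correlation, 3 with fry's directional test and 10 with its mixed test, and 11 to 18 in the other settings, 12 to 17 of them when each array was left out. The matrix, fatty acid oxidation, oxidative phosphorylation, cell cycle, immediate early, fibroblast, fetal and endothelial lists passed in all 22 settings that kept the preset correlation. The developmental regulators were lost in 9 of them, smooth muscle in 7, macrophage and epicardial markers in 4 each, the interferon list in 2 and the adult ventricular list in 1. Of the lists not past the threshold, the unfolded protein list passed in 10 of these 22 settings, the progenitor list in 9, the lymphocyte list in 9 of 21, since too few of its members remained with dim probe sets left out, conduction and nerve markers in 7, ribosome and atrial lists in 4 each, skeletal muscle genes in 3 and circadian genes in 2.

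Some genes and lists changed sign in some settings. Centring turned the PRC1 list to -0.004, Hox genes to 0 and fat markers to -0.012, and leaving out dim probe sets turned fat markers to -0.083. Array weights turned Suz12 to 0.002 and Hox genes to -0.019. The Y-linked covariate turned the ribosome list to -0.025 and neutrophil and mast cell markers to -0.031, and with the letter as well they were -0.006 and -0.02. Without wild-type arrays 4 and 5, Suz12 was 0.016, Hox genes -0.015, glycolysis -0.019 and circadian genes 0.051. Without Ezh2-deficient array 3 as well, Csf3r was -0.026, Suz12 0.05, Hox genes -0.041, circadian genes 0.044, neutrophil and mast cell markers -0.01 and epithelial, lung and thymus markers -0.012. Within letter e, Adgre1 was -0.014, Csf3r -0.079, Suz12 0.097, Hox genes -0.037, circadian genes 0.071, macrophage markers -0.051, neutrophil and mast cell markers -0.07, atrial markers -0.236, fat markers -0.035, conduction and nerve markers -0.027, and epithelial, lung and thymus markers -0.018. Within letter x, the PRC1 list was -0.001 and glycolysis -0.02. Leaving out each array gave -0.073 to 0.043 for fat markers, -0.044 to 0.075 for neutrophil and mast cell markers, -0.066 to 0.218 for atrial markers, -0.012 to 0.03 for Hox genes, -0.009 to 0.061 for glycolysis and -0.044 to 0.094 for the ribosome list. The table gives no signal over background, so no limit by signal was set on any call.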

Other observations

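The test of neighbours of Ezh2 at or above the median level was chosen after the result was seen, and the first test of neighbours before. The remaining lists were not past the camera threshold with all arrays. They were conduction and nerve markers (list mean 0.08, adjusted p = 0.0537), in which Tbx2 differed by 0.12 (SE 0.05), and the unfolded protein and heat shock list (0.12, adjusted p = 0.0642), in which Chac1, a glutathione-degrading enzyme, differed by -0.14 (SE 0.04). Glycolysis had a mean of 0.02 (adjusted p = 0.831), with Eno3, the muscle enolase, at -0.18 (SE 0.05). The ribosome list had 0.04 (adjusted p = 0.203), PRC1 subunits 0.01 (adjusted p = 0.831), circadian genes -0.09 (adjusted p = 0.408), and epithelial, lung and thymus markers 0.03 (adjusted p = 0.291). For neutrophil and mast cell markers (mean 0.02, median 0, adjusted p = 0.763) and fat markers (mean 0.003, median 0.04, lower by the test, adjusted p = 0.936), the mean, median and test did not share a sign. Some of these calls turned on 1 array. Ribosome genes passed without wild-type array 4 (0.09, adjusted p = 6.04e-05) or Ezh2-deficient array 4 (0.08, 0.0201), with 4.52e-06 to 0.847 over all settings, and were -0.04 without Ezh2-deficient array 3; with all arrays the list gave adjusted p = 0.881 with an estimated correlation. Circadian genes passed without wild-type array 1 (-0.20, adjusted p = 0.0258; 0.00543 to 0.903 over all settings), and with all arrays gave adjusted p = 0.805 with an estimated correlation. The unfolded protein and heat shock list passed without wild-type array 2 (0.16, adjusted p = 0.031) or 4 (0.12, 0.0315) or Ezh2-deficient array 2 (0.14, 0.0376) or 3 (0.17, 0.00594), was 0.06 without Ezh2-deficient array 1, and ranged from 0.00218 to 0.521 in adjusted p. With all arrays it gave adjusted p = 0.625 with an estimated correlation. Conduction and nerve markers passed without wild-type array 1 (0.09, adjusted p = 0.0369) or 2 (0.10, 0.027), with 0.0132 to 0.821 over all settings, and with all arrays gave adjusted p = 0.504 with an estimated correlation.

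Genes just outside the threshold, named after their values were seen, include Rpl3l, a muscle-specific ribosomal protein, which was at 9.68 ± 0.28 in Ezh2-deficient and 10.63 ± 0.15 in wild-type hearts, and the desmosomal cadherin Dsg2 (-0.45, SE 0.07, adjusted p = 0.0845). The neural cell adhesion gene Ncam1 differed by 0.58 (SE 0.08, adjusted p = 0.0573).

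A hypothesis set before its values were seen was that alleles linked to the floxed locus, carried over from another strain, may give differences among neighbours of Ezh2. Among the 25 measured genes on each side, 8% had an unadjusted p under 0.05, against a median of 12% and a 95th percentile of 22% over 18842 windows of the same size. This decides little, because 29 of the 50 lay below the median level of all genes and 18 were olfactory or taste receptor genes, which a heart is not expected to use, so the bound set beforehand was not a fair one. Among the 25 genes at or above the median level on each side the share was 26% (exact 95% binomial interval 14.6% to 40.3%, which treats neighbours as independent), against a median of 18% and a 95th percentile of 28% over 8948 such windows, so an excess was neither found nor excluded and the hypothesis stays open. Gene order came from the reference table, and the strain carrying the floxed allele is not stated in the labels. The test bears on the hypothesis only if the wild-type hearts were heterozygous, as their titles name. If they were homozygous floxed, as their genotype field names, both groups would be expected to carry the same linked alleles.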
